A study of Mus musculus with 6 samples.

How the data were processed

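Gene expression was measured by RNA sequencing in CpG-stimulated splenic B cells of 3 female and 3 male NZB/W F1 mice with late disease. The deposited table holds estimated counts for 41669 gene symbols, 1 column per mouse. Per the submitters' processing notes, kallisto and DESeq2 were used with the mouse build GRCm38.p6; their versions, the transcript annotation and the settings are not given in the sources used here. The deposited estimated counts were not scaled to a common depth, and a value of 1 read lay slightly off 1 in each column, so the estimates may have been scaled by transcript length within each library. They were rounded to whole numbers for all count tests. Library totals ran from 24089561 to 35659883. With 3 counts as the floor, the lowest level that could be told from 0 in 1 library was 0.0866 to 0.117 CPM. Intervals and floors cover counting error only.

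Symbols were matched to GENCODE M21 and to RefSeq GRCm38.p6, both on the build the labels name, and 40210 of 41669 symbols (96.50%) found a match, 937 of them through a RefSeq synonym. Coordinates are from these annotations. Older symbols are kept as deposited (Igj is now Jchain, Fam46c is now Tent5c).

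Females were compared with males with edgeR 4.0.16 (R 4.3.3): filterByExpr by sex, TMM factors, estimateDisp, glmQLFit and glmQLFTest with sex as the only term, and Benjamini-Hochberg adjustment at an FDR of 0.05 over 12172 genes. The biological coefficient of variation was 0.351. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Gene lists and X-linked genes were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, inter-gene correlation 0.01, trended variance), with Benjamini-Hochberg adjustment over the 31 lists with at least 3 tested members, and again with an estimated correlation and with fry. All adjusted p values of genes are from edgeR unless another tool is named, and those of lists are from camera. The sexes were from separate mice, so the spread is between animals.

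The test, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named Xist and the Y-linked genes; called genes, up to 12 per direction by size of change, with a mean of at least 5 CPM and no overlap between the sexes, other than predicted or clone names and immunoglobulin or T cell receptor segments; up to 4 called members of each list, or at most the 2 with the smallest p where none was called; and up to 8 further called X-linked genes. Of the genes this rule names, 2 uncalled list members are not reported here. Gapt, Mum1l1, Fam46c, Cxcl13, Msr1 and Hbb-bs were chosen after their values were seen, as were the trended variance option of camera and 3 alternatives: sample quality weights, removal of a trend with transcript length and GC content, and the X-linked set without escape genes, Tsix and Pls3. The trended variance option was set before any camera result was computed. The other alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, library totals only, no filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, each library left out in turn, removal of 315 immunoglobulin genes and robust dispersion. The length and GC trend was fitted per library with natural splines of 4 degrees of freedom each on the longest transcript of each gene, for 98.7% of the tested genes.

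The comparison was tested on simulated data. With counts for the same 12172 genes and 200 changed genes, it recovered 16.25% of genes changed 2-fold, 76.25% of those changed 4-fold and 100% of those changed 16-fold, and 5 of 119 calls were false. The real comparison called 7 genes, and the Benjamini-Hochberg adjustment is stricter where fewer genes pass. These shares may therefore be too high for the real comparison. Of 100 random lists 4 had a camera p under 0.05. Random lists hold no genes chosen to vary together, so this does not test camera on the fixed lists. Those had estimated correlations of up to 0.855 (immunoglobulin constant genes), against the preset 0.01. Figures were drawn with matplotlib 3.10.9.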

Results

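RNA was sequenced from splenic B cells of 6 NZB/W F1 mice, a hybrid strain that develops a lupus-like disease with autoantibodies, at the late stage of that disease. The B cells had been taken from the spleen on a column by positive selection and cultured for 24 h with CpG, a DNA ligand of Toll-like receptor 9 that activates B cells. Of the 6 libraries, 3 came from females and 3 from males, each from a separate mouse. The estimated counts summed to 24089561, 29407229 and 35659883 in female replicates 1 to 3 and to 31550301, 27402953 and 33205284 in male replicates 1 to 3. Of the 41669 genes in the table, 12172 passed the low-count filter. The comparison asks which genes differ between the sexes in activated B cells of diseased mice, and the series title names the inactive X chromosome, so X-linked genes were also tested as a set. Values are CPM, counts scaled to a common library total with TMM factors, as mean ± SD over 3 libraries.

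Female replicate 3 stood apart from the other 5 libraries. It had a score of 94.2 on the first principal component, which held 50.8% of the variance, while the others lay between -47.9 and 6.66. Its TMM factor was 0.816 against 0.993 to 1.07 in the others. Relative to the mean of the other libraries, genes with short transcripts were lower in it, with a median deviation of -0.40 log2 units in the lowest quartile of transcript length and 0.20 in the highest. Across genes, which are not independent replicates, its deviations had a Spearman correlation of 0.24 with transcript length and of -0.58 with GC content. Ribosomal protein genes took 0.692% of its counts (95% Wilson interval 0.689 to 0.695%), against 1.34 to 1.72% in the other 5.

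**Figure D1:**
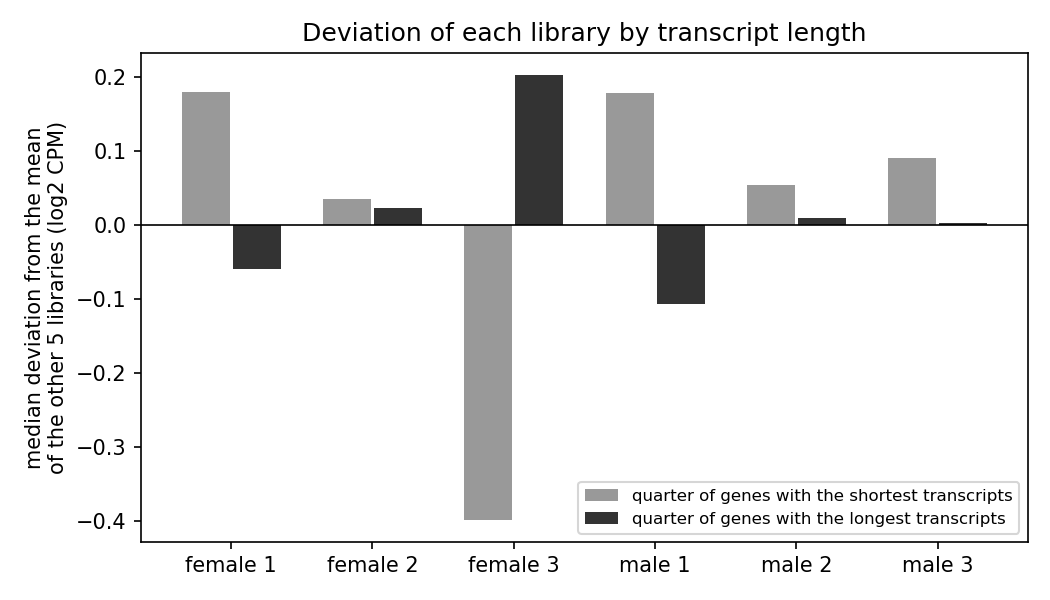
Median deviation of each library from the mean of the other 5 libraries, in log2 CPM, for the genes in the lowest (grey) and the highest (dark) quartile of transcript length. Female 3 lies at -0.40 for the lowest and 0.20 for the highest quartile, and the other libraries lie between -0.11 and 0.18.

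Of the 7 genes called between the sexes, 6 lay on the sex chromosomes. Xist, the noncoding RNA that coats the inactive X chromosome, had 6749 ± 1744 CPM in females and 2.16 ± 0.967 CPM in males, a log2 fold change (female over male) of 11.60 ± 0.52 (SE; adjusted p = 0.00038, edgeR). All 4 Y-linked genes of the fixed list were higher in every male library than in every female one. Ddx3y, an RNA helicase gene, had 187 ± 62.3 CPM in males and 0.917 ± 0.491 CPM in females (log2 fold change -7.65 ± 0.50, adjusted p = 0.00219). Eif2s3y, a translation initiation factor gene, had 144 ± 30.9 and 0.167 ± 0.260 CPM (-9.81 ± 0.75, adjusted p = 0.00417), and Kdm5d, a histone demethylase gene, had 80.8 ± 25.6 and 4.60 ± 1.62 CPM (-4.13 ± 0.37, adjusted p = 0.00983). Female replicate 1 held 12.5 of the female counts of Eif2s3y and the others fewer than 3. Without it the log2 fold change was -12.73, so the printed size rests on that library. Uty had 68.5 ± 8.81 CPM in males and 3.36 ± 2.24 CPM in females (-4.34 ± 0.52), with an adjusted p of 0.0641. Uty passed without female replicate 1 (0.00647) or female replicate 3 (0.0102), and with DESeq2, limma-voom, library totals only, no low-count filter, sample quality weights, the length and GC trend removed or the replicate block (0.00221 to 0.0409 for the last 2). The values of these genes matched the sex given in the labels in 6 of 6 libraries. In GRCm38, Xist lies on chromosome X at 103460366 to 103483254, and the Y-linked genes lie between 897788 (Kdm5d) and 1286629 (Ddx3y) on chromosome Y.

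In all, 7 genes passed an FDR of 0.05, 3 higher in females and 4 higher in males. At an unadjusted p under 0.05 there were 352 genes, against 609 if p values were uniform. Other splits of the libraries into 3 against 3 gave from 101 to 1472 such genes, so 352 lay within their range. DESeq2 called 21 and 11 genes, and limma-voom 3 and 6, or 87 and 142 with sample quality weights, chosen after the data were seen, which ran from 0.201 for female replicate 3 to 4.00 for female replicate 2. Over both directions, autosomal genes made up 21 of the DESeq2 calls, 2 of the limma-voom calls and 210 of those with the weights. Without female replicate 1 or 3 the counts were 6 and 6, without female replicate 2 or male replicate 2 they were 3 and 1, and without male replicate 1 they were 2 and 2. The 3 genes higher in females, Xist, Tsix and Pls3, were all X-linked, of 452 X-linked and 11556 autosomal genes tested. The two-sided Fisher's exact test planned for this count gave p = 5.3e-05. It counts Xist, which is made from the inactive X of females, and Tsix, which overlaps it, so Pls3 is the only separate gene behind it. Tsix, the antisense transcript of Xist, had 29.0 ± 1.53 CPM in females (adjusted p = 0.00118), and its 2435 female counts stood against 2.08 male counts, all in male replicate 3. With male counts rounded to 2 and both sums divided by the library totals, the ratio was 1258 (95% counting interval 348 to 10398). The fitted log2 fold change was 10.19, and 12.72 without male replicate 3, so its size rests on that library. The Tsix gene (X: 103431517 to 103484957) spans Xist on the other strand, and the counting is not stated to use strand. Reads from where the 2 genes overlap may therefore not be told apart, and the share of Tsix reads from outside Xist was not tested. Pls3, which encodes the actin-bundling protein plastin 3 (X: 75785654 to 75875182), had 8.60 ± 1.02 CPM in females and 0.306 ± 0.0843 CPM in males (log2 fold change 4.79 ± 0.37, adjusted p = 0.00417).

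The single autosomal call of the main edgeR fit was Gapt (chromosome 13: 110352616 to 110357199), an adaptor protein gene expressed in B cells, which is named here after its values were seen. It had 0 counts in all 3 female libraries and 179, 148 and 210 estimated counts in the males (adjusted p = 0.0128). In CPM of the library total, without TMM, the males were at 5.81 ± 0.474. Against a floor of 3 counts over the female group on that scale, it was at least 172.5-fold higher in males. Gapt passed in 13 of 18 alternatives, among them DESeq2 (adjusted p = 7.2e-12) and limma-voom (0.00102). Leaving out 1 library ended this call in 4 of 6 fits, those without female replicate 2 or without any one of the males (adjusted p from 0.0505 to 0.224), and so did the replicate block (0.110). Of the other calls, Kdm5d was lost in 3 of these fits (without female replicate 2, male replicate 1 or male replicate 2, up to 0.121), Eif2s3y in 2 (without female replicate 2 or male replicate 2, up to 0.0555), and Pls3 in 2 (without male replicate 1 or 3, up to 0.0579).

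**Figure D2:**
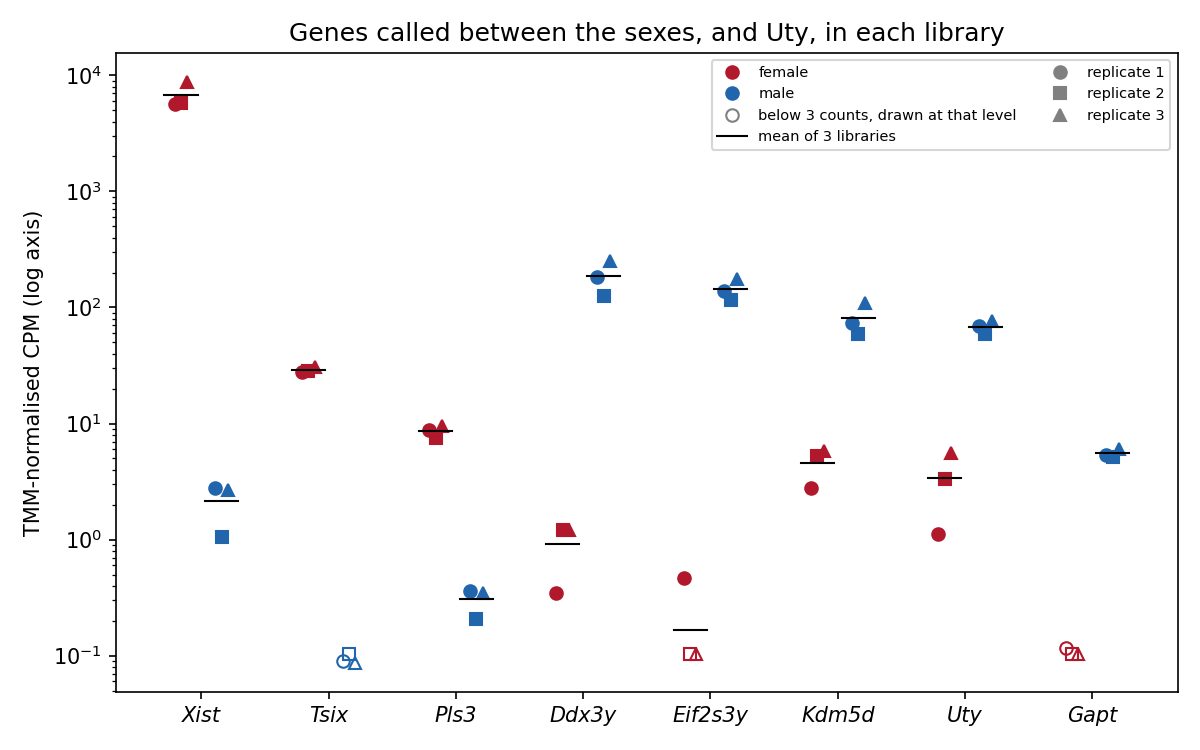
TMM-normalised CPM (log axis) of the 7 called genes and Uty in each library, females in red and males in blue, with symbols for the replicate and a bar at the mean of 3 libraries. Open symbols are values below 3 counts, drawn at that level. The female values of Xist lie between 5657 and 8761 CPM and those of the males between 1.04 and 2.77 CPM, and Gapt is at 0 in each female library.

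Genes known to escape X inactivation lay higher in females. The fixed escape list had 12 tested members, and 12 of 12 had a positive log2 fold change, with a median of 0.55 and 9 of 12 without overlap between the sexes (chance gives 10% of genes). With scaling by library totals only, which lowered the median log2 fold change of all genes by 0.13, 11 of 12 were positive. The list passed limma's camera test at its preset correlation (adjusted p = 5.0e-12 over 31 lists), but not with an estimated correlation between genes (adjusted p = 0.233) or with fry, which tests whether the members move one way (adjusted p = 0.058). No member was called over all genes tested in the main edgeR fit, and 4 passed when adjusted over the list alone. Among them Kdm6a, a histone H3K27 demethylase gene, had 306 ± 84.8 CPM in females and 103 ± 10.3 CPM in males (log2 fold change 1.57 ± 0.22, edgeR adjusted p = 0.147 over all genes, and 3.2e-06 with DESeq2). Eif2s3x had 1192 ± 78.8 and 657 ± 45.7 CPM (0.86 ± 0.14, edgeR adjusted p = 0.283, and 0.00047 with DESeq2). Without female replicate 3 the median was 0.43 and Kdm6a passed the threshold over all genes, as it did without female replicate 1 (adjusted p = 0.0455 and 0.0297). In all, Kdm6a passed in 7 of 18 alternatives.

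The 451 tested X-linked genes other than Xist, a set that holds the escape genes, Tsix and Pls3, had a median log2 fold change of 0.10 against 0.00 for autosomal genes (SD over genes 0.70 and 0.48), and 59.0% of them were positive against 49.8% of autosomal genes. The p of this set with limma's camera was 0.00138. With an estimated correlation the p of this set was 0.130, with fry 0.0617, and without female replicate 3 it was 0.268. With the length and GC trend removed the camera p was 0.0477. With the escape list, Tsix and Pls3 taken out, a choice made after the data were seen, the remaining 437 genes had a median of 0.08 with 57.7% positive, and the camera p was 0.0112 (0.185 with an estimated correlation). The fixed list of X-linked immune genes, which holds the receptor gene Tlr7 and the kinase gene Btk, was not called (18 tested, 10 positive, median 0.02, and -0.13 with library totals only, adjusted p = 0.734). Its members with the smallest p were Tsc22d3, with 17.4 ± 2.31 CPM in females and 23.1 ± 1.26 in males, and Cybb, with 540 ± 101 and 424 ± 39.9.

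Of the 31 lists with at least 3 tested members, 12 passed camera at its preset correlation of 0.01, among them the Y-linked list (adjusted p = 1.1e-19) and the escape list. Only the Y-linked list kept its call with an estimated correlation (adjusted p = 0.0286) and with fry (0.00154). The calls of the other lists below therefore hold only under the preset correlation. None of their members was called over all genes tested in the main edgeR fit, while DESeq2 called members of the macrophage list, among them Lyz2 and Spic.

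Cholesterol synthesis genes and interferon-stimulated genes were lower in females. Of the cholesterol synthesis list, 16 of 19 tested members had a negative log2 fold change, with a median of -0.37 (adjusted p = 5.5e-07; 0.453 with an estimated correlation), and 0 passed when adjusted over the list alone. Nsdhl had 46.0 ± 8.44 CPM in females and 75.0 ± 9.15 in males, and Msmo1, which like Nsdhl acts late in sterol synthesis, had 280 ± 35.3 and 392 ± 60.0. Without female replicate 3 the list's median was -0.19 (adjusted p = 5.0e-05). Of the interferon-stimulated list, 21 of 23 members were negative, with a median of -0.44 (adjusted p = 2.1e-06; 0.453 with an estimated correlation), and 0 passed over the list alone. Its members with the smallest p, the antiviral genes Ifit1 (0.176 ± 0.0861 against 0.980 ± 0.816 CPM) and Oas1a (0.416 ± 0.299 against 1.14 ± 0.194 CPM), were near the lower limit of the counts.

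Genes of the Xist RNA interactor and Polycomb list and of the monocyte and macrophage list were higher in females. Of the first, 23 of 29 tested members were positive, with a median of 0.24 (adjusted p = 0.000374; 0.453 with an estimated correlation) and 0 past the threshold over the list alone. Ezh2, the H3K27 methyltransferase gene of Polycomb complexes, had 508 ± 80.1 CPM in females and 391 ± 62.1 in males, and Tardbp had 1454 ± 467 and 1062 ± 106. Without female replicate 3 this list's median was 0.11 (adjusted p = 0.0417), with library totals only it was 0.11 (18 of 29 positive), and with the length and GC trend removed 0.09. Of the macrophage list, 8 of 11 members were positive (7 of 11 with library totals only), with a median of 0.92 (adjusted p = 0.000374; 0.453 with an estimated correlation), and 3 passed when adjusted over the list alone. Levels were low: Lyz2, a lysozyme gene of myeloid cells, had 2.78 ± 0.554 CPM in females and 0.308 ± 0.0584 in males (log2 fold change 3.15 ± 0.40, edgeR adjusted p = 0.0837 over all genes). Lyz2 passed with DESeq2 (5.1e-08) and with the length and GC trend removed (0.0320). Spic, a transcription factor gene of red pulp macrophages, had 1.52 ± 0.582 and 0.330 ± 0.0400 (2.19 ± 0.45, edgeR adjusted p = 0.797, and 0.0493 with DESeq2).

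**Figure D3:**
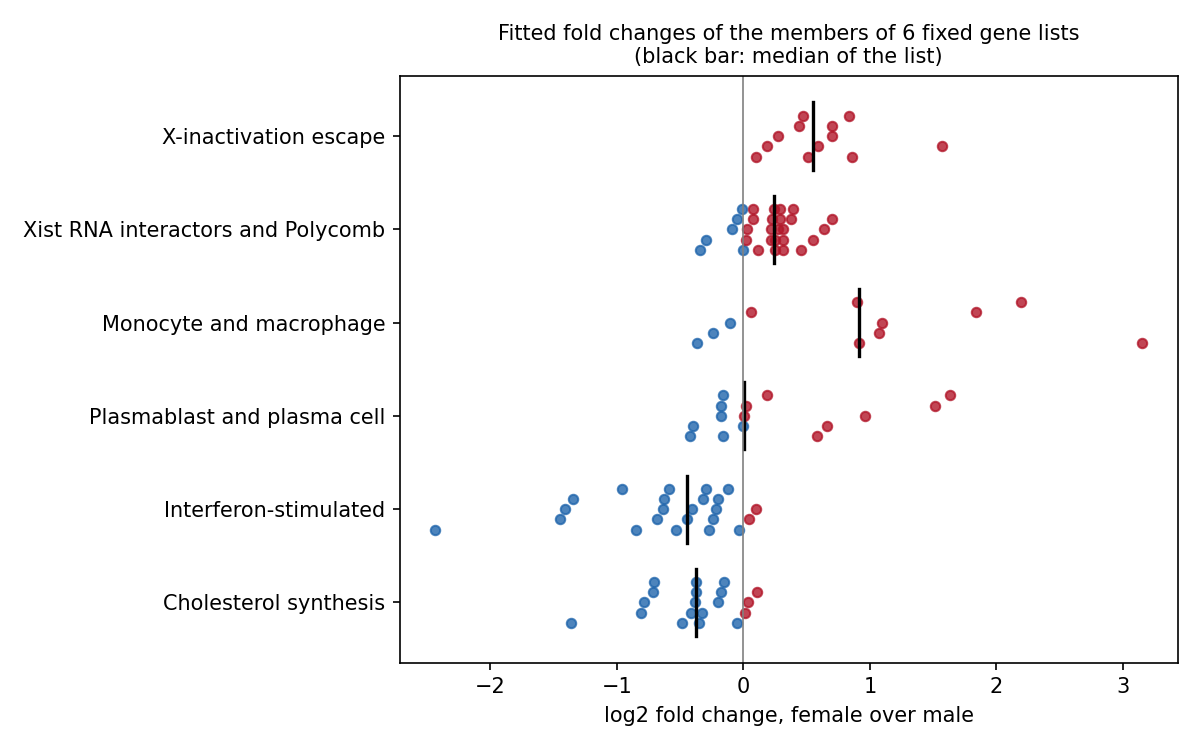
Fitted log2 fold changes (female over male) of the tested members of 6 fixed gene lists, 1 point per gene, red above 0 and blue below, with a black bar at each list's median. All 12 escape genes lie above 0 here (11 of 12 with library totals only), 8 of 11 macrophage genes do (7 of 11), 21 of 23 interferon-stimulated genes lie below it, and the medians run from 0.92 for the macrophage list to -0.44 for the interferon-stimulated list.

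The remaining called lists depended on single libraries, most often female replicate 3. Ribosomal protein genes (57 of 78 negative, median -0.20, adjusted p = 0.000152), nuclear genes of oxidative phosphorylation (50 of 66 negative, -0.16, 0.00717) and immunoglobulin constant genes (8 of 9 negative, -0.18, 0.0119) turned to positive medians of 0.10, 0.04 and 0.17 without that library. Mitochondrially encoded genes (13 of 14 positive, median 0.25, adjusted p = 0.0119) then had a median of 0.03, while camera pointed downwards (adjusted p = 0.689), and they were also not called without male replicate 2 (0.121). Glycolysis and hypoxia genes (17 of 22 negative, -0.17, 0.00365) had a median of 0.10 without female replicate 3 while camera pointed downwards (0.689). They were also not called without female replicate 2 or male replicate 1 (0.0741 and 0.0705), and the oxidative phosphorylation list was not without male replicate 1 (0.312). With an estimated correlation the adjusted p of these 5 lists was 0.769. Members with the smallest p included some against the direction of their list. Rps9 had 96.4 ± 30 CPM in females and 66.0 ± 18.0 in males, and Rpl23 694 ± 43.8 and 821 ± 41.4. Atp5s had 9.48 ± 2.04 and 4.51 ± 2.54 CPM, and the complex I genes mt-Nd3 and mt-Nd5 442 ± 276 against 227 ± 72.4 and 5707 ± 2318 against 4051 ± 338. Ighd, the IgD constant gene, had 33.7 ± 6.29 CPM in females and 50.2 ± 4.40 in males, Ighg2b 83.8 ± 18.7 and 94.7 ± 3.10, Vegfa 4.86 ± 1.84 and 8.68 ± 3.05, and Hif1a 261 ± 71.1 and 204 ± 9.10. Ribosomal protein genes as a family took 1.25 ± 0.520% of counts in females and 1.57 ± 0.132% in males (exact permutation p = 0.5, 2-sided; the smallest that 3 against 3 allows is 0.1), with female replicates 1 and 2 at 1.72 and 1.34%.

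Replication-dependent histone genes, at 10 of 12 negative (median -0.56, adjusted p = 0.00948; 0.580 with an estimated correlation), were low in both sexes. Hist2h2be had 4.40 ± 0.590 CPM in females and 7.15 ± 2.45 in males, and Hist1h1c 0.95 ± 0.0717 and 2.50 ± 1.96. This call ended without female replicate 1, female replicate 2 or male replicate 2 (adjusted p = 0.0680, 0.139 and 0.0791). With the trend with transcript length and GC content removed, the histone (0.0638), ribosomal protein (0.241), oxidative phosphorylation (0.546) and immunoglobulin constant (0.129) lists were no longer called. Their medians were then -0.50, -0.17, -0.09 and -0.10, so those of the histone and ribosomal protein lists stayed near -0.56 and -0.20.

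Lists of B cell states gave no call. Calls that other settings added to these and the next lists are at the preset correlation, since an estimated correlation was run with all 6 libraries and no trend removed only. The plasmablast and plasma cell list had 8 of 15 members positive, a median of 0.00 (-0.11 with library totals only) and a mean of 0.27 (adjusted p = 0.135), and 3 members passed when adjusted over the list alone. Igj, the joining chain gene of secreted antibody, had 47.7 ± 11.9 CPM in females and 16.7 ± 0.749 in males (log2 fold change 1.51 ± 0.22, edgeR adjusted p = 0.169 over all genes, 0.0297 without female replicate 1, and 4.4e-06 with DESeq2). Prdm1, the transcription factor gene that drives plasma cell differentiation, had 36.9 ± 22.0 and 11.9 ± 0.697 CPM (1.63 ± 0.39, edgeR adjusted p = 0.999, and 0.0253 with DESeq2). Without female replicate 3 the list passed (median 0.11, adjusted p = 0.0312), as it did with the length and GC trend removed (0.0109). With all libraries its adjusted p was 0.759 with an estimated correlation and 0.817 with fry. The age-associated B cell list (9 of 13 positive, median 0.23, adjusted p = 0.113) also passed without that library (0.30, 0.00936). Its median was 0.04 with the trend removed (7 of 13 positive, 0.199) and 0.06 with library totals only. Its adjusted p was 0.453 with an estimated correlation. In it Fgl2 had 24.2 ± 10.1 CPM in females and 10.2 ± 2.85 in males, and the costimulator gene Cd86 had 16.2 ± 1.39 and 12.1 ± 0.860. Without female replicate 3, 52 of 62 immunoglobulin heavy variable and 59 of 68 kappa variable genes were positive (adjusted p = 0.000199 and 2.0e-06). With it 23 of 58 and 28 of 62 were (adjusted p = 0.795 and 0.295; 0.953 and 0.846 at estimated correlations of 0.460 and 0.602), and in both the median was negative and the mean positive. The medians were 0.14 and 0.08 with the trend removed, and the heavy variable list then passed (0.00626). The naive and follicular list (14 of 21 negative, median -0.14, adjusted p = 0.135, and 0.00881 with the trend removed) included Fcer2a, the CD23 gene, at 1.59 ± 0.633 CPM in females and 4.97 ± 2.56 in males. The marginal zone and B1 list had 8 of 15 positive (median 0.05, and -0.04 with library totals only, adjusted p = 0.538), with the complement receptor gene Cr2 at 206 ± 12.3 and 162 ± 6.90 CPM and Il10 at 15.0 ± 10.7 and 7.01 ± 2.66. The germinal centre list had 8 of 12 positive (median 0.05, and -0.08 with library totals only, mean -0.11, 0.736), with Gcsam at 0.448 ± 0.657 and 1.67 ± 0.488 CPM and Rgs13 at 3.21 ± 1.26 and 5.17 ± 0.923.

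Signalling and stress lists also stayed above the threshold. The TLR9 and NF-kB response list had 13 of 36 positive (median -0.11, adjusted p = 0.506, and 0.14 without female replicate 3), with the transcription factor gene Irf4 at 171 ± 49.3 CPM in females and 114 ± 15.8 in males and Bcl2a1b at 239 ± 29.9 and 308 ± 30.1. B cell receptor signalling had 9 of 24 positive (-0.06, 0.488, and 0.05 without that library), with the phosphatase gene Ptpn22 at 62.7 ± 15.4 and 43.2 ± 5.82 CPM and Nfatc1 at 22.3 ± 8.80 and 14.0 ± 1.99. MHC class II and antigen presentation had 6 of 17 positive (-0.12, 0.0805), with H2-D1 at 48.9 ± 9.14 and 62.2 ± 2.13 CPM and Tap1 at 8.02 ± 3.37 and 12.3 ± 2.01, and passed with the replicate block (0.0362). The cell cycle list had 14 of 37 positive (-0.04, 0.666), with Gins2 at 12.05 ± 0.400 and 9.63 ± 1.46 CPM and Ccna2 at 594 ± 390 and 386 ± 143. The unfolded protein response list had 12 of 22 positive (median 0.03, and -0.10 with library totals only, mean -0.12, 0.660), with Chac1 at 1.013 ± 0.446 and 2.07 ± 0.148 CPM and Asns at 101 ± 40.8 and 163 ± 21.1. Dissociation and heat-shock stress had 8 of 14 positive (0.08, and -0.04 with library totals only, 0.538), with Atf3 at 21.2 ± 12.1 and 35.8 ± 2.97 CPM and Junb at 1.27 ± 0.158 and 0.723 ± 0.207. Oestrogen and androgen response genes gave 0.239 (5 of 13 positive, -0.02, and 0.01 with RLE factors), with Ccnd1 at 0.690 ± 0.323 and 1.08 ± 0.0374 CPM, and passed without female replicate 3 (median -0.20, 0.0312). Genes of lupus risk and B cell tolerance gave 0.722 (14 of 31 positive, -0.06, and 0.03 without female replicate 3), with Dnase1l3, a nuclease gene that degrades extracellular DNA, at 1.04 ± 0.346 CPM in females and 2.63 ± 0.775 in males.

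Markers of other cell types than macrophages were not called in the main fit, and single members went both ways. DESeq2 called the erythroid gene Hbb-bs higher in females (log2 fold change 4.79, adjusted p = 0.0493), and Ccr9 of the dendritic cell list passed in 1 of 18 alternatives. T cell genes had 2 of 7 members positive (median -0.30, adjusted p = 0.736), with Cd3d, a T cell receptor complex gene, at 3.19 ± 0.969 CPM in females and 0.937 ± 0.840 in males and Cd247 at 7.66 ± 4.42 and 12.8 ± 4.70. Dendritic cell genes had 3 of 7 positive (median -0.20, mean 0.12, 0.660), with the chemokine receptor gene Ccr9 at 4.36 ± 2.49 and 1.43 ± 0.576 CPM and Tcf4 at 211 ± 45.3 and 153 ± 18.4. Stromal and endothelial genes had 3 of 4 positive (median 0.07, and -0.13 with library totals only or without female replicate 3, mean 0.00, 0.660), with Pecam1 at 29.9 ± 9.76 and 38.6 ± 1.85 CPM and Col1a2 at 0.820 ± 0.329 and 0.700 ± 0.120. Of the natural killer, neutrophil, erythroid and immunoglobulin lambda variable lists 2 members each passed the filter, so these lists were not tested. Their medians were 0.23, -0.06, 0.20 and -0.07. Klrb1c had 4.15 ± 2.90 CPM in females and 2.35 ± 1.11 in males, Rora 0.539 ± 0.489 and 0.694 ± 0.519, Cxcr2 0.975 ± 0.300 and 1.07 ± 0.240, and Mmp8 4.32 ± 3.54 and 4.30 ± 1.03. Tfrc, the transferrin receptor gene, had 1866 ± 262 and 1600 ± 32.6 CPM, and Car2 had 8.35 ± 6.08 and 7.39 ± 5.06. The fitted directions of Ccna2, Rora, Cxcr2, Mmp8, Car2 and Col1a2 reversed when single libraries were left out.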

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

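The tests with sample quality weights, with the length and GC trend removed and with a reduced X-linked set were chosen after the data were seen. Xist, Tsix and Ddx3y were called under all 18 alternatives, and none of the 7 called genes changed direction. DESeq2 called 21 genes higher in females (6 X-linked) and 11 higher in males, sample quality weights 87 (10 X-linked) and 142, the removal of the trend 5 higher in females, and no low-count filter 5. Leaving out 1 library gave 2 to 6 genes higher in females and 1 to 6 higher in males. X-linked genes as a set had p = 0.1304 with an estimated correlation and 0.06172 with fry, and from 0.0007235 to 0.2683 when 1 library was left out, the highest without female replicate 3. With the trend removed the camera p of this set was 0.04773. Of the lists, 1 was called with an estimated correlation and 1 with fry. Whether the replicate numbers pair the samples was not settled. The correlations of deviations were low but positive (0.22, 0.04 and 0.07), with 4 of 6 libraries closest to their own number, and pairing was not tested. The fit with the replicate number as a block called 3 and 4 genes, with Uty gained (adjusted p = 0.0409) and Gapt lost (0.1104), and 13 lists. Without female replicate 3 the direction reversed for immunoglobulin constant genes (adjusted p over the left-out libraries 0.001361 to 0.5952), ribosomal protein genes (1.365e-09 to 0.1043), mitochondrially encoded genes (9.828e-05 to 0.6893) and oxidative phosphorylation genes (3.318e-05 to 0.6365), where the upper value is the one without it. Named genes that reversed had not been called. Their log2 fold changes over the left-out libraries ran from -0.06993 to 0.8909 for Ccna2, -1.438 to 0.3497 for Rora, -0.3419 to 0.09475 for Cxcr2, -0.9264 to 0.3815 for Mmp8, -0.6149 to 0.8936 for Car2 and -0.1292 to 0.4876 for Col1a2. With quality weights Ccna2 was at -0.1371, Col1a2 at -0.2347 and Mmp8 at -0.8855. With library totals only Car2 was at -0.04457 and Mmp8 at -0.2218. Mmp8 was also at -0.2567 with limma-voom, -0.04029 with upper-quartile factors, -0.007414 with the stricter filter, -0.2689 with the block and -0.1852 with the trend removed. The cause of these changes was not tested. Of the other values for single genes, 1205 kept direction and side of the threshold, 48 newly passed it and 12 lost it; of those for the 12 called lists and the plasmablast and age-associated lists, 140, 3 and 34 did. On simulated data of the same depth and number of mice, with 200 changed genes, 16.25% of 2-fold and 76.25% of 4-fold changes were recovered. With fewer changed genes these shares may be lower.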

Other observations

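The tests on the splits, the T cell comparison, the macrophage list without the trend and the 31-mers of Gapt were chosen after the result was seen, while those on female replicate 3 and on the second myeloid list were written before. Inside the fixed lists, DESeq2 called genes that the main fit did not, among them Kdm6a, Eif2s3x, Igj, Prdm1, Lyz2 and Spic, with values given above. Outside the fixed lists, 4 genes named here after their values were seen were higher in every female library than in every male one, and passed with DESeq2 but not with edgeR. Fam46c, a gene expressed strongly in plasma cells, had 102 ± 43.6 CPM in females and 40.8 ± 4.44 in males (log2 fold change 1.32 ± 0.29, edgeR adjusted p = 0.876, and 0.0201 with DESeq2). The X-linked gene Mum1l1 had 3.02 ± 0.390 and 0.384 ± 0.180 CPM (2.97 ± 0.45, adjusted p = 0.204, and 6.3e-07 with DESeq2). Msr1, a macrophage scavenger receptor gene, had 1.27 ± 0.466 and 0.118 ± 0.0791 CPM (adjusted p = 0.450, and 0.00509 with DESeq2), and Cxcl13, a B cell attracting chemokine gene, had 0.701 ± 0.361 and 0.00963 ± 0.0167 CPM (adjusted p = 0.315, and 0.0284 with DESeq2). Immunoglobulin genes took 0.149 ± 0.0722% of counts in females and 0.174 ± 0.00721% in males (exact permutation p = 0.8). The lower female mean rests on female replicate 3 at 0.0694%, while the other females were at 0.210 and 0.168%.

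With 3 mice against 3 there are 10 splits of the 6 libraries, too few for a share under 0.05. The real split called 7 genes and the highest of the other 9 called 0, so 1 of 10 reached the real count. All but 1 of these 7 lay on the sex chromosomes, and those on the Y chromosome and Xist follow from sex itself. The reads of Tsix may not be told apart from those of Xist. Autosomal calls numbered 1 in the real split and 0 in the others. For lists, the real split called 12 and the highest of the others also 12, so 2 of 10 did. The Y-linked and escape lists are tied to sex itself. Without them the real split called 10 lists. The split of female 1, male 1 and male 2 called 11, and those of female 1 with female 3 and male 3, or with male 2 and male 3, called 10. For the X-linked set the camera p was 0.00138 in the real split and 0.00206 as the smallest of the others, so 1 of 10 reached it. The split of female 1, male 1 and male 3 against the rest had 1472 genes at an unadjusted p under 0.05 against 352 in the real one (0 and 7 called). This points to a structure of the libraries other than sex, and these 3 had the highest correlations of deviations with GC content across genes, which are not independent replicates (0.50, 0.44 and 0.25). Camera p values were smallest in the real split for the Y-linked, escape, cholesterol synthesis, interferon-stimulated and macrophage lists, and for the naive and follicular list, which was not called. By chance alone a list ranks first in the real split 1 time in 10, so some of the 31 lists would do so without any sex difference. Other splits gave smaller ones for the Xist interactor list (3.5e-05 against 8.3e-05) and for the ribosomal protein, glycolysis, oxidative phosphorylation, mitochondrial, histone and immunoglobulin constant lists.

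The distance of female replicate 3 from the other libraries went with transcript length and GC content, which explained 29.8% of its deviations across genes, against 0.229 to 17.4% in the others. The trend was not the whole cause: once it was removed, the mean correlation of that library with the others was 0.953, up from 0.946, while the other 5 lay between 0.965 and 0.974. Deeper sequencing did not account for it either, since with all libraries thinned to the smallest total its mean correlation was 0.947 and the lowest in 10 of 10 draws. A difference in RNA quality or library preparation may contribute, and a difference in the state of the cells of that mouse stays open. No biological explanation was tested, since the pattern is in 1 mouse.

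The higher level of macrophage genes in females could come from macrophages carried over the column that selected the B cells. In a second list of 34 myeloid genes, none shared with the first and 7 of them at 5 CPM or more in males and so also expressed in these cultures, 22 were tested and the median log2 fold change was 0.163 (13 positive, camera 0.309), which leaves the carry-over open; its most abundant members went both ways, with Ms4a6c at 646 and 687 CPM in females and males, Mpeg1 at 87.8 and 61.0 and Ctsb at 34.7 and 35.9. A lower share of B cells would raise all other cell types alike, and the T cell median of -0.30 with 2 of 7 positive runs against it, but the macrophage median exceeded that by 1.212 with p = 0.0903 (exact permutation test over 11 and 7 genes), which does not exclude it. Genes are not independent replicates, so this p does not measure the spread between mice. The length and GC trend was not the whole cause, as the macrophage list kept an adjusted p of 0.0001196 with it removed (9.2e-07 to 0.00949 over the left-out libraries). A sex difference within the B cells stays open and untested.

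Gapt at 0 in every female library is a pattern of absence rather than of degree. Reads shared with other transcripts are unlikely as a cause, since 0% of the 2079 31-mers of its 2 GENCODE M21 transcripts lie in transcripts of other genes, although the index behind the estimates is not given in the sources used here. Estimates of 0 beside higher ones also occurred elsewhere, as 47 genes, Gapt included, were at 0 in at least 1 library and at 5 CPM or more in another. Eif2s3y and Tsix, whose zeros go with sex, are also among these genes. Of the 10 splits, 2 had a gene at 0 in 3 libraries and above 1 CPM in the others, with 1 such gene in the real split and 1 as the highest of the others. The comparison of the sexes called Gapt (edgeR adjusted p = 0.0128), as did 13 of 18 alternatives. The replicate block and 4 fits with 1 library left out lost the call, so a sex difference stays open.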
